A study of Mus musculus with 8 samples.

How the data were processed

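RNA from mouse liver was measured on 8 Agilent 2-colour arrays, 2 per group, in female and male controls and in females and males given IL1-beta. Per the labels, total RNA was extracted with Trizol, liver was labelled with Cy5 and universal mouse reference RNA with Cy3. The deposited values are log10 ratios of the 2 channels of each feature. Agilent Feature Extraction is named in the submitters' processing notes, without a version, and the background correction and the dye normalization are not given in the sources used here. The log10 base was not stated and was checked on the values: 373 of 6110 unnamed features measured on all arrays fell into 9 clusters of near-equal values (32 to 64 features each, DBSCAN with eps 0.12 and at least 12 neighbours). The clusters spanned 1.51 to 1.71 units on the 8 arrays. Spike-in mixtures of 10:1 to 1:10 would span 2 units on a log10 scale, so the resemblance is rough, and the steps were not tested. Medians of single clusters also moved by 0.21 to 0.84 units between arrays. The lowest r between 2 arrays over these clusters was 0.850. Channel intensities were not analysed here, so signal over background is unknown.

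Log10 ratios were multiplied by 3.32 to give log2 ratios. An exact 0 was taken as no measurement, and 32366 features had another value on all 8 arrays. Of these, 26218 carried 1 gene symbol and gave 15346 genes, each as the mean of its probes (6485 genes had more than 1 probe). Values were otherwise used as deposited. A linear model with the 4 group means was fitted with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (4 residual and 2.88 prior degrees of freedom), so that all groups share 1 estimate of the spread. Contrasts were the IL1-beta effect in females, in males and averaged over the sexes, their interaction, and the sex difference in controls and under IL1-beta. Tests were two-sided, and p-values were adjusted over all genes by Benjamini-Hochberg, with 0.05 as the threshold. Errors given with log2 values are standard errors of the contrast. The design took the reference to be shared by all arrays, which the control arrays did not meet. A sex difference on the control arrays with its sign turned and divided by 2, and the interaction with it, were therefore added after the data were examined. All other comparisons, the gene lists and the rule for named genes were fixed before the data were examined.

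In total 46 lists of pathway genes and cell type markers were fixed, with 1105 genes, of which 1003 were on the array and 956 were tested. Lists were tested with limma's camera, with the inter-gene correlation preset to 0.01 and, as an alternative, estimated for each list, and adjusted over the 46 lists of a contrast. No list passed in any contrast with an estimated correlation. Members passing were counted over all genes and adjusted over the list alone. A Kruskal-Wallis test of whether cell type lists move apart was tried and set aside, since the genes of a list are not independent. The rule for named genes took, among passing genes whose arrays did not overlap between the sides compared (within each sex for the averaged effect, no such condition for the interaction), the 10 with the largest positive and the 10 with the largest negative change. It added up to 4 passing members of each list, or up to 2 with the smallest p where none passed, and the sex chromosome genes. The text names a selection from these, with fewer genes for contrasts that compare unlike arrays.

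Alternatives were array median centring, quantile normalization, probes with at least 1 value in each group, leaving out the 25% of genes with the lowest mean ratio, testing every probe, the probe with the highest mean ratio, eBayes with trend and robust, array weights, a replicate block, a fit of the compared groups only, an additive model, an adjusted p under 0.10, a 2-fold minimum, and leaving out each array. Exact zeros kept as values, control arrays with the sign turned, a crossed block, and pair means of control arrays were added after the data were examined. The method was tested on simulated data with 200 changed genes among 15346: a log2 change of 2 was recovered in 64% of genes for the sex difference under IL1-beta, 96% for that on the control arrays after turning and 52% for their interaction. A log2 change of 1 was recovered in 18%, 70% and 12%. On the control arrays the change was entered in both groups with opposite signs, as the turned and divided form assumes. The gap between groups was therefore larger there than under IL1-beta, and the recovered shares are not like for like. False calls made up 7.1%, 5.3% and 0.83% of all calls in these comparisons. Noise was drawn independently, with the same SD for a gene on every array. Correlated deviations between control arrays are therefore not covered.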

Results

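Liver RNA of male and female C3H/HeN mice was hybridised to Agilent 2-colour arrays. Mice of 8 weeks received vehicle or 25 µg/kg recombinant murine IL1-beta intraperitoneally every other day for 2 weeks. Livers were taken 1 h after the last injection. The series has 8 arrays in 4 groups of 2, which are female control, male control, female IL1-beta and male IL1-beta. According to the labels, each array holds liver in Cy5 and universal mouse reference RNA, a pool of 11 mouse cell lines, in Cy3. Each array gives 45018 ratios, of which 33653 carry 1 gene symbol, 56 carry several and 11309 carry none. Exact zeros, taken as features without a measurement, numbered 7933, 10324, 8711 and 9272 on the control arrays (female 1 and 2, male 1 and 2). They numbered 5035, 5024, 4646 and 5115 on the IL1-beta arrays in the same order. Column medians over all features, exact zeros included, were 0 on 7 arrays and -0.00129 (log10) on the female IL1-beta array 2. Since exact zeros count in them, these medians do not show that the arrays are centred. Over the tested genes, medians (log2) lay between -0.143 and -0.081 on the IL1-beta arrays and between -0.018 and 0.013 on the control arrays. Tests covered 15346 genes. The number of arrays, 2 per group, limits the precision of every value. Beyond the words "biological replicate", the labels give nothing on how the replicates were obtained, so the p-values measure the spread between the 2 arrays of each group.

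The IL1-beta arrays had the profile of liver over a cell-line pool. Medians of the hepatocyte list (Alb, Apoa1, Ttr, Cps1 and others, 11 genes measured) were 5.85 and 5.65 (log2) on the female and 5.75 and 6.11 on the male IL1-beta arrays. Medians of 33 cell cycle genes were -2.94, -3.42, -3.32 and -3.62. On the arrays labelled control, the hepatocyte list lay at 0.00 and -0.28 (labelled female) and at 0.16 and 0.16 (labelled male). The cell cycle list lay there at -0.34, 0.21, 0.47 and -0.02. Xist, the RNA that silences an X chromosome in female cells, read 2.11 and 1.52 on the female and -4.32 and -4.36 on the male IL1-beta arrays, as their labels give. On the arrays labelled female control it read -4.94 and -4.57, and on those labelled male control 5.40 and 5.78. The Y-linked gene Eif2s3y, a translation initiation factor, read 10.03 and 10.80 on the arrays labelled female control and -9.17 and -10.56 on those labelled male control. Across the tested genes, which are not independent replicates, female and male control arrays of the same number correlated at r = -0.722 and -0.592. Those of unlike number correlated at r = -0.519 and -0.478. Within the female control arrays r was 0.628 and within the male control arrays 0.613. Correlations among the IL1-beta arrays were between 0.942 and 0.973. The control arrays thus differ from their labels in 2 measured respects, the absence of a liver signal over the pool and the sign of the sex chromosome genes.

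**Figure D1:**
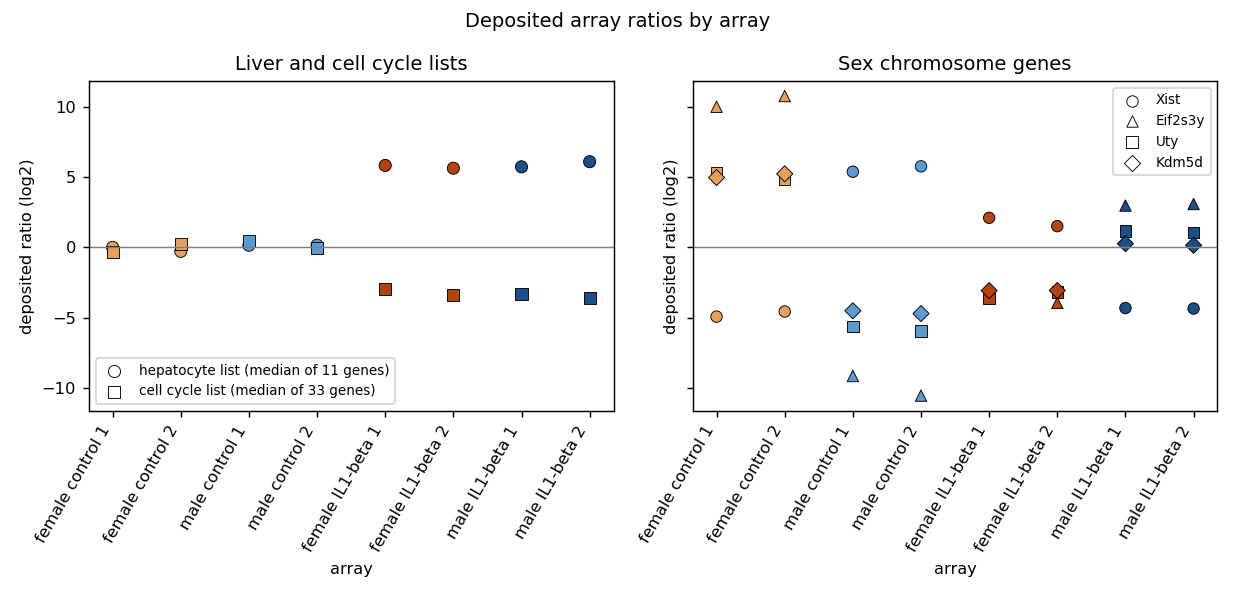
Deposited ratios (log2) on each of the 8 arrays, 1 point per array and measure, with list medians on the left and 4 sex chromosome genes on the right. The hepatocyte list lies between 5.65 and 6.11 on the IL1-beta arrays and between -0.28 and 0.16 on the arrays labelled control, where Xist and the Y-linked genes have the sign opposite to the label.

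The sex difference under IL1-beta was read from 4 arrays that share a profile. Its standard errors and p-values also use the spread of the control arrays, which lack that profile. The sulfotransferase Sult3a1 was higher in females by 8.04 ± 0.37 (log2, SE, n = 2 arrays per sex, adjusted p = 0.000679). Of the same enzyme family, Sult2a2 was higher by 5.59 ± 0.47 and Sult2a4 by 5.48 ± 0.49. Also higher in females were Hao2, a peroxisomal hydroxyacid oxidase (7.62 ± 0.53), and Cux2, a transcription factor of female mouse liver (5.59 ± 0.22). The transporters Slc22a29 (5.80 ± 0.41), Abcd2 (3.96 ± 0.36) and Slc22a26 (3.29 ± 0.28) were higher in females too. Higher in males were the Y-linked genes Eif2s3y (-6.71 ± 0.48, female minus male), Uty (-4.54 ± 0.26) and Kdm5d (-3.28 ± 0.19). The lipocalin Obp2a (-4.29 ± 0.31), the potassium channel Kcnk1 (-4.26 ± 0.38) and the glutathione transferase Gstp1 (-3.10 ± 0.28) were higher in males as well. Nat8f5 (-4.62 ± 0.39), Nat8 (-1.88 ± 0.19) and the carboxylesterase Ces2b (-1.91 ± 0.20) followed. Xist was higher in females by 6.15 ± 0.27 and Cyp2b13, a cytochrome P450, by 2.94 ± 0.23. In all, 25 genes passed the limma test at an adjusted p of 0.05, 16 higher and 9 lower in females. The adjusted p of these named genes lay between 0.000626 (Cux2) and 0.0225 (Ces2b).

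Of 59 measured genes of the female-biased liver list, 10 were higher and 0 lower in females, or 25 higher and 2 lower when adjusted over the list alone. Its median was 0.79 (camera adjusted p = 4.40e-18 with the preset correlation, adjusted p = 0.447 with an estimated correlation). The male-biased list had 3 of 44 genes lower and 1 higher in females, or 13 and 1 adjusted over the list alone. Its median was -0.60 (adjusted p = 3.94e-13, and adjusted p = 0.447 with an estimated correlation). The gene of that list with the opposite direction was Dntt, terminal deoxynucleotidyl transferase, at 1.96 ± 0.20. Fatty acid synthesis genes had a median of 0.79 over 24 genes, with 0 passing over all genes and 10 higher adjusted over the list alone. The camera test gave an adjusted p = 7.48e-09 (adjusted p = 0.447 with an estimated correlation). Acacb, an acetyl-CoA carboxylase, stood at 1.43 ± 0.21 (adjusted p = 0.0830) and Srebf1, a regulator of lipid synthesis, at 1.33 ± 0.21 (adjusted p = 0.103). Among 10 NK cell genes 0 passed and 3 were higher adjusted over the list alone, with a median of 0.68 (adjusted p = 0.00249, and adjusted p = 0.447 with an estimated correlation). Cd7 stood at 1.43 ± 0.33 (adjusted p = 0.275) and the granule protein gene Nkg7 at 0.86 ± 0.26 (adjusted p = 0.380). None of 30 acute phase and 13 negative acute phase genes passed over all genes or over the list alone, with medians of -0.22 and -0.28. Both lists had a camera adjusted p of 0.00489 and an adjusted p of 0.447 with an estimated correlation. Fgb, a fibrinogen chain, stood at -0.75 ± 0.20 (adjusted p = 0.334) and Alb at -0.61 ± 0.18 (adjusted p = 0.378). No gene of the JAK-STAT list passed, and Osmr, a subunit of the oncostatin M receptor, stood at -1.32 ± 0.24 (adjusted p = 0.156). Got1, an aspartate aminotransferase of the amino acid catabolism list, stood at 1.55 ± 0.23 (adjusted p = 0.0758).

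A fit of the 4 IL1-beta arrays alone, with fewer arrays to estimate the spread, gave 10 genes. Quantile normalization of all arrays, which forces the same distribution on arrays of unlike spread, left 5 genes, 4 higher and 1 lower in females. Without 1 of the 4 IL1-beta arrays the count was 10 or 14 (female 1 or 2) and 7 or 10 (male 1 or 2). Of all tested genes 1270 had an unadjusted p under 0.05, and 5656 genes (36.9%) did not overlap between the 2 female and 2 male arrays, where chance gives 33.3%.

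As labelled, the sex difference in controls had Y-linked genes higher in females and Xist higher in males. Eif2s3y was higher on the arrays labelled female by 20.28 ± 0.48 (n = 2 arrays per label, adjusted p = 4.58e-06), Uty by 10.89 ± 0.26 and Kdm5d by 9.73 ± 0.19. Xist stood at -10.34 ± 0.27. A total of 3284 genes passed, 1427 higher and 1857 lower on the arrays labelled female, and 10348 (67.4%) did not overlap, where chance gives 33.3%. Since the signs of Xist and of the Y-linked genes oppose the labels and the female and male control arrays mirror each other, the difference was also taken with its sign turned and divided by 2. This form was added after the values had been seen. It leaves the tests of each gene as they were and gives 1857 genes higher and 1427 lower in the direction of Xist, called the Xist side here. These tests take the control arrays as independent. If same-number arrays share RNA, they are not, and the standard errors and p-values that follow would be too small. The count from means of same-number pairs is given below.

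On the Xist side were Sult3a1 (8.13 ± 0.18, adjusted p = 4.58e-06), Hao2 (6.74 ± 0.27), Slc22a26 (6.05 ± 0.14), Sult2a4 (4.55 ± 0.24), Sult2a2 (4.33 ± 0.23) and Cux2 (2.99 ± 0.11). These genes were also higher in females under IL1-beta. Cyp4a14, a fatty acid hydroxylase, stood on the same side at 5.03 ± 0.17, the transcription factor gene Ebf3 at 4.59 ± 0.15, Tmem182 at 4.47 ± 0.59 and the aspartate acetyltransferase gene Nat8l at 4.22 ± 0.31. On the opposite side were Nat8f5 (-5.57 ± 0.20), Kcnk1 (-4.33 ± 0.19), the glutamate receptor gene Grm8 (-3.94 ± 0.13), Pramel34 (-3.84 ± 0.34), Nat8 (-3.81 ± 0.09), Obp2a (-3.73 ± 0.15) and the trefoil factor gene Tff3 (-3.55 ± 0.16). The female-biased list had 48 of 59 genes on the Xist side and 3 opposite, or 50 and 4 adjusted over the list alone. Its median was 1.62 (camera adjusted p = 5.46e-26, adjusted p = 0.146 with an estimated correlation). The male-biased list had 27 of 44 genes opposite and 2 on the Xist side, or 31 and 3 adjusted over the list alone. Its median was -0.88 (adjusted p = 1.49e-12, and adjusted p = 0.296 with an estimated correlation). Cytochromes P450 went both ways, 25 of 58 toward the Xist side and 7 opposite, or 31 and 8 adjusted over the list alone. Cyp2c38 (4.15 ± 0.16) and Cyp2b9 (4.10 ± 0.14) were on the Xist side, and Cyp4a12a (-3.35 ± 0.16) and the oxysterol hydroxylase Cyp7b1 (-2.53 ± 0.19) opposite. The list median was 0.33 (adjusted p = 4.69e-05, and adjusted p = 0.492 with an estimated correlation). Of 40 PPARa targets and fatty acid oxidation genes 16 passed, all on the Xist side (21 adjusted over the list alone). Among them were the pyruvate dehydrogenase kinase Pdk4 (3.71 ± 0.25) and the pantetheinase Vnn1 (2.64 ± 0.26). Their camera adjusted p was 6.60e-08, and the adjusted p = 0.217 with an estimated correlation.

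**Figure D2:**
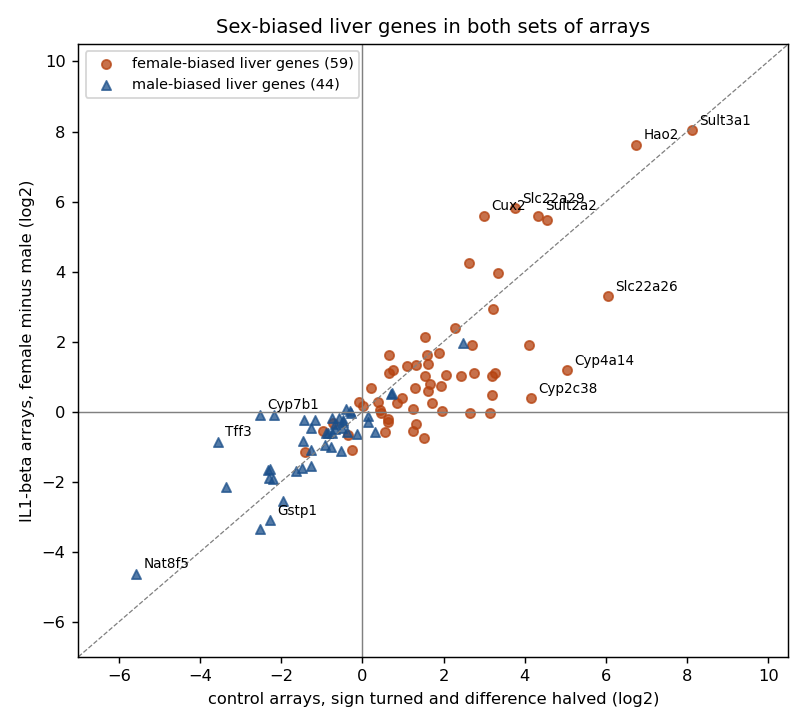
Difference between the sexes (log2) of 59 female-biased and 44 male-biased liver genes, with the control arrays, sign turned and divided by 2, on the horizontal axis and the IL1-beta arrays, female minus male, on the vertical axis. Each point is 1 gene, the dashed line marks equal values, and 49 female-biased and 39 male-biased genes have the same sign on both axes.

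Extracellular matrix genes lay on the Xist side in 16 of 23 cases (18 adjusted over the list alone). The collagen chain Col1a1 stood at 2.34 ± 0.12, the thrombospondin gene Thbs1 at 2.18 ± 0.23 and the list median at 0.76 (camera adjusted p = 4.74e-10, adjusted p = 0.0843 with an estimated correlation). Stellate cell markers followed, with 11 of 15 genes (13 adjusted over the list alone) and a median of 0.57 (adjusted p = 2.09e-07, and adjusted p = 0.174 with an estimated correlation). Of 7 adipose and mesothelium genes 6 passed, both over all genes and adjusted over the list alone. Their median was 1.98 (adjusted p = 0.000293, and adjusted p = 0.217 with an estimated correlation). The 2 arrays labelled male control were unlike each other in adipocyte genes. Plin1, the fat droplet coat protein, read -0.10 and 5.35, the hormone gene Adipoq 1.08 and 4.19, and Cidea 2.19 and 4.15. The arrays labelled female control were closer, with Plin1 at -4.09 and -4.65, Adipoq at -3.29 and -3.22 and Cidea at -3.10 and -3.07. Col1a1 (2.52 and 2.36) and Ebf3 (4.29 and 4.72) were close between the same arrays. Interferon response genes lay on the Xist side in 19 of 35 cases (23 adjusted over the list alone). The GTPase Gbp3 stood at 2.19 ± 0.14, Oasl2 at 1.47 ± 0.10 and the list median at 0.51 (adjusted p = 6.52e-09, and adjusted p = 0.288 with an estimated correlation). Kupffer cell and macrophage markers did so in 8 of 13 cases (10 adjusted over the list alone). The scavenger receptor Marco stood at 1.24 ± 0.17, Cd5l at 0.97 ± 0.12 and the list median at 0.87 (adjusted p = 2.09e-05, and adjusted p = 0.296 with an estimated correlation). Other members on the Xist side were the metallothioneins Mt1 (1.97 ± 0.24) and Mt2 (2.15 ± 0.38), the hepcidin gene Hamp2 (1.94 ± 0.17) and the cyclin Ccnd1 (1.73 ± 0.16). The complement gene C6 lay opposite at -2.28 ± 0.20. The hepatocyte list had 1 of 11 genes passing and a median of 0.18 (camera adjusted p = 0.157).

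**Figure D3:**
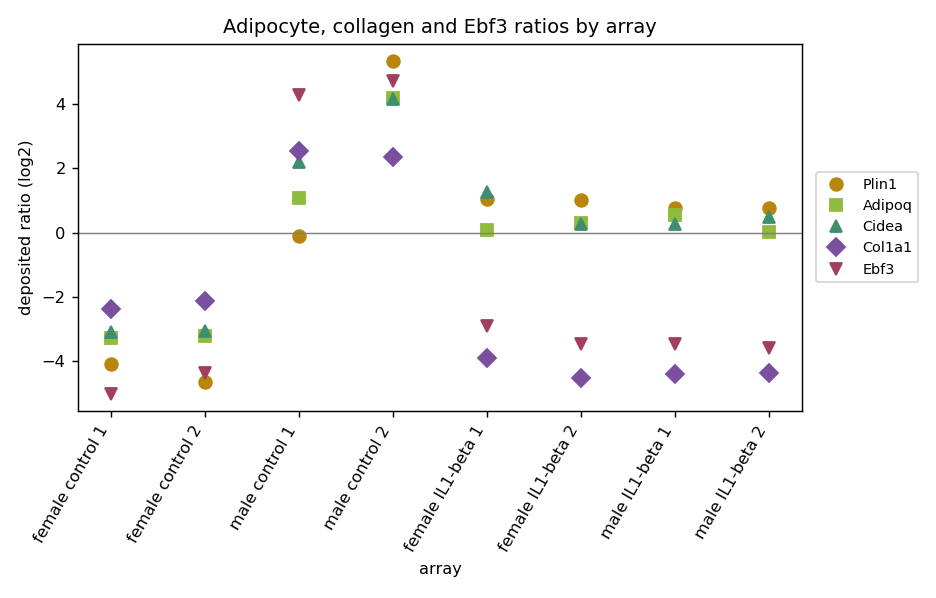
Deposited ratios (log2) of 3 adipocyte genes (Plin1, Adipoq, Cidea), the collagen gene Col1a1 and Ebf3 on each of the 8 arrays, 1 point per gene and array. Plin1 reads -0.10 and 5.35 on the 2 arrays labelled male control and -4.09 and -4.65 on those labelled female control, while Col1a1 reads 2.52 and 2.36 on the arrays labelled male control.

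All 25 genes that differed between the sexes under IL1-beta had the same sign on the control arrays after turning and 0 of them as labelled. Of these, 24 also passed there. Among the 25 are Xist, Eif2s3y, Uty and Kdm5d, whose signs prompted the turning, so their match was fixed beforehand. The values correlated at r = 0.962 across the 25 genes, with a median ratio of 0.885 between control and IL1-beta arrays. Without those 4 genes the ratio was 0.869, and r was not computed. Selection of the 25 genes under IL1-beta can lower this ratio. Across all tested genes r was 0.439. Among the 3284 genes that passed on the control arrays, 2436 (74.2%) had the same sign under IL1-beta. Their median absolute difference was 0.69 on the control arrays, where they were selected, and 0.28 under IL1-beta. Leaving out 1 control array brought the 3284 genes to 2013 or 1728 (female 1 or 2) and to 1516 or 2077 (male 1 or 2), and 884 genes differed by at least 2-fold. Means of same-number pairs of control arrays gave 1087 genes, the count that uses no RNA more than once if such arrays share it.

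The question whether the sexes responded differently was put to the interaction. As labelled, 2189 genes passed, 1322 with a higher and 867 with a lower IL1-beta effect in females. The count was 837 to 1579 without 1 array, 4103 after quantile normalization and 561 with the sign of the control arrays turned. Sult3a1 stood at 24.30 ± 0.52 (adjusted p = 5.48e-06), Xist at 16.50 ± 0.38, Eif2s3y at -26.99 ± 0.69 and Nat8f5 at -15.77 ± 0.55. These values contain the control difference in its labelled sign. With the control difference turned and divided by 2, 32 genes passed, 4 with a higher and 28 with a lower female-minus-male value under IL1-beta than on the control arrays. Among the 4 were Cux2 (2.61 ± 0.24, adjusted p = 0.0203) and G6pc, the glucose-6-phosphatase gene (3.13 ± 0.37, adjusted p = 0.0383). Among the 28 were Ebf3 (-4.26 ± 0.34, adjusted p = 0.0130), the heart-type fatty acid binding protein Fabp3 (-3.83 ± 0.28, adjusted p = 0.0106) and the cytochrome oxidase subunit Cox8b (-3.41 ± 0.24, adjusted p = 0.0106). The chemokine Ccl11 (-4.02 ± 0.36, adjusted p = 0.0203) and Cyp4a14 (-3.85 ± 0.38, adjusted p = 0.0252) were lower as well. Of 7 adipose and mesothelium genes 0 passed, 1 was lower adjusted over the list alone and 0 had a positive value. Their median was -1.16 (camera adjusted p = 0.00363, adjusted p = 0.280 with an estimated correlation). Whether adipose tissue in single control samples contributes to the values of this contrast was not tested. Cytochromes P450 had 4 of 58 genes lower, or 16 lower and 3 higher adjusted over the list alone. Cyp2c38 stood at -3.76 ± 0.36, Cyp2a4 at -3.18 ± 0.29 and Cyp2c39 at -1.80 ± 0.19 (list median -0.29, camera adjusted p = 1.13e-07, adjusted p = 0.280 with an estimated correlation). PPARa targets and fatty acid oxidation genes had 1 of 40 lower, or 7 adjusted over the list alone, with a median of -0.50 (adjusted p = 2.89e-10, and adjusted p = 0.266 with an estimated correlation). Of 23 extracellular matrix genes 0 passed and 8 were lower adjusted over the list alone. Their median was -0.60 (adjusted p = 5.45e-08, and adjusted p = 0.126 with an estimated correlation), and Col1a1 stood at -2.17 ± 0.28 (adjusted p = 0.0513). The female-biased list had 1 gene higher and 5 lower of 59, or 2 and 16 adjusted over the list alone. Its median was -0.53 (adjusted p = 1.79e-06, and adjusted p = 0.280 with an estimated correlation), and Slc22a26 stood at -2.76 ± 0.31 (adjusted p = 0.0374). Osmr at -2.07 ± 0.27 (adjusted p = 0.0513), Tff3 at 2.69 ± 0.36 (adjusted p = 0.0546) and Cyp7b1 at 2.45 ± 0.42 (adjusted p = 0.110) did not pass. With limma, 0 genes passed with the replicate number as a block (1261 at an unadjusted p under 0.05) or without any 1 of the 4 IL1-beta arrays (1077 to 1989), 9 with means of same-number control arrays, and 6 and 10 without female control array 1 and 2. Quantile normalization gave 628 genes, 45.4% of them higher against 12.5%, and turned the value of Cux2 to -0.54 (adjusted p = 0.387).

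The comparison of IL1-beta with control, the subject of the series, set the liver profile of the IL1-beta arrays against control arrays without one. Acute phase genes were higher on the IL1-beta arrays in 29 of 30 cases (29 adjusted over the list alone), with Crp at 8.66 ± 0.22 (n = 4 arrays per treatment), the heme carrier Hpx at 8.48 ± 0.24 and Steap4 at 7.46 ± 0.15. The list median was 5.72. Negative acute phase genes, whose products fall in inflammation, were higher in 13 of 13 cases (13 adjusted over the list alone), with a median of 6.16. Of 17 neutrophil genes 14 were higher (S100a9 6.84 ± 0.32, Retnlg 6.70 ± 0.22) and 3 lower, which were Mmp9, Clec4d and Clec4e, named after their values were seen. Of 13 Kupffer cell and macrophage genes 12 were higher (Clec4f 6.54 ± 0.12, Cd5l 6.87 ± 0.17) and 0 lower, and of 15 genes of sinusoidal endothelium 14 were higher (Lyve1 6.67 ± 0.17) and 0 lower. Adjusted over the list alone, counts higher and lower were 14 and 3, 12 and 1, and 14 and 0. So were the chemokines Cxcl10 (6.79 ± 0.25) and Cxcl9 (6.05 ± 0.24), Il1b itself (5.96 ± 0.41), the decoy receptor Il1r2 (6.54 ± 0.25) and the receptor antagonist Il1rn (5.14 ± 0.30). Higher values were also those of Icam1 (5.26 ± 0.13), Cd83 (6.29 ± 0.22) and the GTPase Iigp1 (7.47 ± 0.16). The succinate receptor gene Sucnr1 stood at 10.98 ± 0.36. Named liver enzymes and carrier proteins had values between 6.94 and 10.07, namely Mup6 (10.07 ± 0.35), Cyp2c54 (9.57 ± 0.17), Fabp1 (9.32 ± 0.21), Pck1 (7.85 ± 0.20), Igfbp1 (7.27 ± 0.17) and Otc (6.94 ± 0.16). All 33 cell cycle genes were lower (33 adjusted over the list alone), with Bub1 at -6.12 ± 0.28. Also lower were the kinesin Kif18a (-7.68 ± 0.23), Bnc1 (-7.11 ± 0.26), Aspn (-6.51 ± 0.17), Fos (-4.55 ± 0.12), Col1a1 (-4.40 ± 0.18) and the bile duct keratin Krt19 (-3.06 ± 0.25). With an estimated correlation the adjusted p was 0.0700 for acute phase genes, 0.0809 for negative acute phase genes and 0.206 for the cell cycle list.

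In this contrast 10620 genes passed, 4856 higher and 5764 lower on the IL1-beta arrays, against 8774 in females (3959 and 4815) and 9444 in males (4511 and 4933). In females Sult3a1 stood at 18.40 ± 0.37, Hao2 at 15.65 ± 0.53, Eif2s3y at -14.09 ± 0.48, Uty at -8.50 ± 0.26 and Kif18a at -7.17 ± 0.33. In males Eif2s3y stood at 12.91 ± 0.48, Obp2a at 11.29 ± 0.31, Xist at -9.93 ± 0.27 and Kif18a at -8.19 ± 0.33. Both sexes passed in 6908 genes, of which 6624 had the same sign. Across genes, the contrast correlated at r = 0.993 with the mean ratio of the IL1-beta arrays alone, and its SD was 2.01 against 2.00. The mean ratio of the control arrays correlated with that of the IL1-beta arrays at r = -0.003. The values averaged over the sexes are therefore nearly those of IL1-beta liver over the cell-line pool, with little subtracted. This does not hold within 1 sex, where the control arrays can contribute much of a value. Sult3a1 averaged 10.55 on the female IL1-beta arrays, against 18.40 in the contrast in females. With the sign of the control arrays turned, 10947 genes passed, 9641 in females and 8920 in males. Centring each array on its median moved the median of all genes from -0.12 to -0.02, and in females from -0.19 to -0.05.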

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

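Except for the count over other splits of the arrays, the tests of explanations in this part were chosen after the result was seen, as were the turned interaction, its alternatives and the turned control sign.

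The interaction of sex and IL1-beta passed in 2189 genes as labelled (837 to 1579 without 1 array, 4103 after quantile normalization, 561 with the control sign turned), with Sult3a1 at 24.30, Xist at 16.50, Eif2s3y at -26.99 and Nat8f5 at -15.77, and the test was of the difference between the effects in females and males itself; the control arrays behind it lie near 0 for liver genes and opposite between the sexes. Exchanged sex labels on arrays with the shared reference are argued against by the hepatocyte list, whose highest median on a control array was 0.16 against a lowest of 5.65 on an IL1-beta array. Centring of each gene over the control arrays by the authors would leave a mean or median of 0 and is argued against by SDs of 0.318 and 0.336 (log2) of the mean and the median of the 4 control arrays over 32693 features. A candidate explanation is that each control array holds female and male liver, with the dyes swapped between the arrays labelled female and male. The control difference turned and divided by 2 was compared in the 25 genes that differed between the sexes under IL1-beta. Its median ratio to the difference under IL1-beta was 0.885, or 0.869 without the 4 sex chromosome genes whose signs prompted the turning. These genes were selected by a large difference under IL1-beta, which can lower the ratio, so the ratio cannot decide on this explanation. In the sex-biased lists, fixed beforehand, the female-biased median was 1.62 on the control arrays after turning and 0.79 under IL1-beta. For male-biased genes the medians were -0.88 and -0.60. The labels, however, state another second channel. The sex of the animals is part of the mirrored values, as the signs of Xist and Eif2s3y on these arrays show, and under that hypothesis the turned and divided difference is the sex difference of liver from control mice.

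After turning and dividing by 2, the interaction passed in 32 genes, again by the test of the difference itself. With the replicate number as a block 0 passed (limma, 1261 at an unadjusted p under 0.05), and with means of same-number control arrays 9 passed. Positive values were those of G6pc (3.13), Cux2 (2.61), Grm8 (2.46) and Nat8 (1.93). Negative values of named genes were Ebf3 at -4.26, Ccl11 at -4.02, Kcna1 at -3.94, Ebf1 at -3.91, Cyp4a14 at -3.85, Fabp3 at -3.83, Cyp2c38 at -3.76, Rbp7 at -3.59, Cox8b at -3.41, Vit at -3.22, Cyp2a4 at -3.18, Slc22a26 at -2.76 and Cyp2c39 at -1.80.

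Adipose and matrix genes were on the Xist side on the control arrays and 0 of them passed under IL1-beta. Matrix genes carried by single samples are argued against by all 23 measured genes of that list, whose median differed by at most 0.0448 (log2) between arrays of 1 control group. A lower share of hepatocytes in females stays open. The medians of 11 lists of other liver and blood cells ran from -0.03 to 0.88, a range of 0.911. The prediction for this cause, all medians above 0 and within a narrower range, was missed. The bound set for arguing against it, a range over 1, was not reached either. Of the T cell list 3 genes passed on the Xist side and 4 opposite. The hepatocyte list, not among these lists, had a median of 0.18, with 8 of 11 genes positive, 1 passing on the Xist side and 0 opposite. That is not the direction of a lower share, but the list did not pass (camera adjusted p = 0.157 with the preset correlation). Adipose tissue in single samples stays open. The median of the adipocyte genes Plin1, Adipoq and Cidea differed by 3.10 between the arrays labelled male control (1.08 and 4.19). It differed little between those labelled female control (-3.29 and -3.22), and all 4 arrays lay on the Xist side. The whole adipose and mesothelium list was closer between the arrays labelled male control, with medians of 1.47 and 1.20. A difference between the sexes in matrix genes that IL1-beta narrows stays open and was not tested apart from the unlike form of the control arrays.

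A total of 10620 genes differed between IL1-beta and control arrays. Of the 35 splits of the 8 arrays into 4 and 4, 1 gave as many genes, the real one. In a model with treatment and sex it gave 9428, against 20 in the highest other split. This share cannot fall below 1 of 35, so chance is not excluded. The real split also separates arrays with a liver profile from arrays without one. It shows that these sets of arrays are unlike, not that IL1-beta made them so. Control arrays without liver over the shared reference may account for most of the values, as the highest r across genes of a control array with the mean ratio of the IL1-beta arrays was 0.135. An effect of IL1-beta stays open as an added part, untested because no array with control liver over the shared reference was found among the 8.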

How the results depend on the processing

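Exact zeros kept as values, turned control arrays, pair means, the crossed block and every alternative of the turned results were chosen after the data were seen, and the other alternatives before. Of 3066 values of 137 named results under the alternatives, 2782 kept direction and side of the threshold, 255 lost the call, 16 gained one and 13 reversed. All 653 values of the averaged IL1-beta effect kept both, and so did 969 of 975 on the control arrays after turning, with 6 losing the call. Under IL1-beta, 91 of 613 values for the sex difference lost the call. Sult3a1 and Cux2 passed there in every alternative run. In the turned interaction 158 of 456 values lost the call. Channel intensities were not analysed here, so the limit set by signal over background is unknown.

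Quantile normalization stretches the control arrays, whose SD over tested genes is 0.66 to 0.74 against 1.99 to 2.07 on the IL1-beta arrays. It gave 6614 genes for the averaged effect, 5084 in females, 4103 for the interaction, 6765 for the sex difference in controls (6765 turned), 5 for the sex difference under IL1-beta and 628 for the turned interaction, where Cux2 reversed to -0.54 (adjusted p = 0.387). Without the 25% of genes with the lowest mean ratio, which removes genes low in liver, counts were 6867 (69.8% higher) for the averaged effect, 5502 (70.1%) in females, 5885 (75.1%) in males, 1443 for the interaction and 19 for the turned interaction. Testing every probe gave 19 and keeping exact zeros 11 for the turned interaction. The causes of the last changes were not tested. A fit of the compared groups only, with fewer arrays to estimate the spread, gave 2058 genes in controls (2058 turned) and 10 under IL1-beta. An adjusted p under 0.10 gave 3565 for the interaction, 58 under IL1-beta and 75 for the turned interaction, and a 2-fold minimum left 884 on the control arrays after turning.

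Leaving out each array gave 837 to 1579 genes for the interaction, 1516 to 3130 for the sex difference in controls (also turned), 7 to 23 under IL1-beta and 0 to 27 for the turned interaction. Without 1 array the lone array of its group is assumed to vary like the other groups. The interaction gave 1389 and 1387 genes without female control 1 and 2, 1246 without male control 1, 1326 without female IL1-beta 1, and 968 and 837 without male IL1-beta 1 and 2. Controls gave 2013 and 1728 without female control 1 and 2, and 1516 and 2077 without male control 1 and 2. Under IL1-beta the count was 10 and 14 without female IL1-beta 1 and 2, and 7 and 10 without male IL1-beta 1 and 2. The turned interaction gave 0 without any 1 of the IL1-beta arrays, and 6 and 10 without female control 1 and 2 (limma, unadjusted p under 0.05 in 1077 to 1989 genes).

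With the replicate number as a block, the interaction gave 1383 genes and the turned interaction 0 (limma, 1261 at an unadjusted p under 0.05). Other blocked counts were 10194 for the averaged effect, 8139 in females, 8893 in males, 2433 in controls and 18 under IL1-beta. The labels do not pair the numbers. Deviations of same-number arrays correlated across genes at -0.43 between female and male controls and at -0.41 between female and male IL1-beta arrays, and between -0.04 and 0.05 elsewhere, so a block with crossed numbers was added, which gave 3433 genes in controls and 34 under IL1-beta. Means of same-number pairs of control arrays, used as single values after turning, gave 1087 genes for the sex difference and 9 for the turned interaction, and means of crossed pairs 1927 and 127. The pair means leave fewer values per group. The labels do not say whether same-number control arrays share RNA, and the 1087 genes are the count that would not use such samples more than once.

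With the sign of the control arrays turned, the interaction passed in 561 genes. By construction the sex difference in controls then reverses its sign. Other values reverse only where the part from the control arrays is larger than that from the IL1-beta arrays. Eif2s3y was then 6.74 and Uty 1.68 for females, and Eif2s3y -6.82 and Xist 1.25 for males. The interaction was -8.22 for Sult3a1, -4.19 for Xist, 13.57 for Eif2s3y and 6.52 for Nat8f5, and the sex difference in controls 10.34 for Xist, -20.28 for Eif2s3y, -10.89 for Uty and -9.73 for Kdm5d. With an estimated correlation 0 lists passed in each of the 8 contrasts, against 34 (averaged), 34 (females), 31 (males), 18 (interaction), 19 (controls, and 19 turned), 19 (under IL1-beta) and 22 (turned interaction) with the preset value. The lowest adjusted p with an estimated correlation was 0.0532, in females.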

Other observations

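The test in the last paragraph of this part was chosen after the result was seen.

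On the control arrays after turning, further lists lay mostly on the Xist side. Of 26 coagulation genes 7 passed, all on that side (7 adjusted over the list alone), with a median of 0.24 (camera adjusted p = 0.000769, adjusted p = 0.296 with an estimated correlation). Of 14 monocyte and dendritic cell genes 6 passed on that side, or 8 and 1 opposite adjusted over the list alone (median 0.64, adjusted p = 0.00125, and adjusted p = 0.288 with an estimated correlation). Of 17 neutrophil genes 6 did, or 7 adjusted over the list alone (median 0.56, adjusted p = 0.00334, and adjusted p = 0.520 with an estimated correlation), and of 10 NK cell genes 6, or 8 adjusted over the list alone (median 0.88, adjusted p = 0.000182, and adjusted p = 0.276 with an estimated correlation). Complement genes went both ways, with 6 of 25 on the Xist side and 7 opposite, the same counts adjusted over the list alone. The cell cycle list had 1 of 33 genes on the Xist side, Ccnd1, and 3 opposite, also adjusted over the list alone.

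Under IL1-beta, sinusoidal endothelial genes had a median sex difference of 0.42 over 15 genes, of which 14 were positive and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.00489, adjusted p = 0.559 with an estimated correlation). Immediate early genes, which respond within an hour to many stimuli, had a median of 0.23 over 31 genes with 0 passing over all genes and 1 higher adjusted over the list alone (adjusted p = 0.00897, and adjusted p = 0.447 with an estimated correlation). The T cell list had 0 of 12 genes passing over all genes or adjusted over the list alone and a median of 0.23 (adjusted p = 0.159).

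Of 44 male-biased liver genes, 31 had a larger difference between the sexes on the control arrays after turning than under IL1-beta. The same held for 38 of 59 female-biased genes, so it was not particular to the male-biased list. The hypothesis that IL1-beta may narrow the difference in male-biased genes was tested on the turned interaction. There the male-biased list had a median of 0.21 and a camera adjusted p of 0.691 with an estimated correlation (0.0213 with the preset one). This leaves the hypothesis undecided.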
